A study of Mus musculus with 13 samples.

How the data were processed

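RNA was measured in whole lower incisors of male mice on postnatal day 5, with 5 libraries of controls, 3 of VDRgem mutants and 5 of VDR-null mutants. Per the labels' protocols, stranded poly-A libraries were made from 300 ng of total RNA with 12 PCR cycles. The deposited counts per gene were made by the authors with bcl2fastq 2.20.0.422, STAR 2.5.3a on mm10 and HTSeq 0.6.1p1, per the submitters' processing notes. The annotation release, the counting mode, the strand setting and any filter on genes are not given in the sources used here. The values were whole numbers without scaling for 34709 Ensembl genes and 13 libraries, of which 1143 genes had no count. Every column was matched to a library. No library was a copy of another, since the smallest chi-square per degree of freedom was 15.2 between replicates and 24.6 between libraries of different groups.

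Gene symbols, coordinates and transcript GC content came from GENCODE M21 on GRCm38, the assembly called mm10. A symbol was found for 34618 genes, and genes without one held at most 0.00145% of a library's counts. Total counts ran from 20405188 to 87783466 per library. Levels are CPM after TMM scaling, and a list's level is its mean log2 CPM with a prior count of 2. SD describes the spread between libraries and SE the error of a fitted log2 fold change.

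Genes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, after TMM scaling and filterByExpr with a minimum count of 10, which kept 17837 genes. All 13 libraries entered 1 fit with a mean per group and no covariate, so the groups shared their spread. Each of the 3 comparisons used the quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, and genes with an adjusted p under 0.05 were called. The Vdr level was also tested with an exact permutation test of log2 CPM.

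A set of 35 gene lists was written from general knowledge of tooth and vitamin D biology before the data were examined. The same holds for the tests and for the rule that picked the genes named. The lists held 452 distinct members measured here, 43 of them in more than 1 list. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with the correlation estimated from these libraries and with fry. A member counted as risen or fallen when it passed over all genes, and a further count, adjusted over the list alone, used only the p-values of that list. The rule named Vdr first. It then took, in each comparison with control, up to 8 rises and 8 falls by size (6 each between the mutants) among genes with a mean of at least 1 CPM, an adjusted p under 0.05 and every mutant library on the same side of every control. It also took up to 3 members of each list by smallest p, and up to 6 genes each way that passed in both mutants. A few further genes were named from short counts, without values, after their values were seen. A few list members that entered the tests are not reported here by name.

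Overlap between the mutants was set against 40 simulations of unchanged groups with the same controls, against independent lists of the same sizes, and against 20 fits that divided the controls between the mutants. Genes within 10 Mb of Vdr were compared with all other tested genes by Fisher's exact test.

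Alternatives were DESeq2 1.42.0, limma-voom, other size factors, no low-count filter, a mean of at least 1 CPM, robust dispersion, only the groups compared, 1 surrogate variable (sva 3.50.0), other thresholds, leaving out each library, and other region sizes. Alternatives added after results were seen were an offset for a smooth GC trend per library (spline with 5 degrees of freedom), the fit without VDRgem 1 and 2, the keratinocyte score as a covariate, and the region without keratin genes. A fit that leaves 1 VDRgem library assumes that it varies like the other groups. The tests were tried on simulated counts with 200 genes changed by known folds and on simulated list changes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.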

Results

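RNA-seq counts were analysed for 13 libraries of whole lower incisors from male mice on postnatal day 5. The mouse incisor grows throughout life, so each tooth holds dividing cells at its apical end and mature enamel- and dentin-forming cells towards its tip. Of these libraries, 5 came from wild-type controls, 3 from VDRgem mutants and 5 from VDR-null mutants. Both mutants carry an altered vitamin D receptor gene, Vdr. VDRgem is a receptor mutant known to respond to synthetic gemini analogs but not to the natural hormone, and VDR-null mice are known to lack a working receptor. The incisors are described as independent, but the animal behind each library is not named, so p-values measure the spread between these incisors. Total counts per library ran from 20405188 in control 2 to 87783466 in VDRgem 3.

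The targeted gene was read out in every library before any comparison. Vdr (ENSMUSG00000022479) lies on the minus strand of chromosome 15 from 97854425 to 97910630 in the mm10 assembly and is annotated as protein-coding. Its level was 164 ± 15.8 CPM in controls (SD, n = 5), 164 ± 50.9 CPM in VDRgem (n = 3) and 242 ± 32.7 CPM in the libraries labelled VDR-null (n = 5). The VDRgem libraries held 107, 205 and 179 CPM, and all 5 VDR-null libraries, at 204 to 281 CPM, lay above the highest control at 180 CPM. A two-sided exact permutation test on log2 CPM gave p = 0.00794 for VDR-null against control, the smallest that its arrangements allow, and p = 0.911 for VDRgem against control. In edgeR's quasi-likelihood test across all genes the log2 fold changes were 0.56 (SE 0.15, adjusted p = 0.0619) and -0.00 (SE 0.17, adjusted p = 0.998). VDRgem 1 enters the VDR-null comparison only through the shared spread, the gene filter and the scaling. Leaving VDRgem 1 out gave an edgeR adjusted p of 0.0254 for VDR-null. VDRgem lay below VDR-null by a log2 fold change of -0.56 (SE 0.18, adjusted p = 0.0397, exact permutation p = 0.0357). Without VDRgem 1 that value was -0.34 with an edgeR adjusted p of 0.166. It also missed the threshold without VDR-null 1, 2, 3 or 5 (0.0501, 0.0702, 0.0522 and 0.0759) and without control 1, 2, 3 or 4 (0.0504, 0.0533, 0.0599 and 0.0503). A count per gene does not show which exons the reads came from, so a transcript that is made but altered leaves these values high and they do not check the labels.

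**Figure D1:**
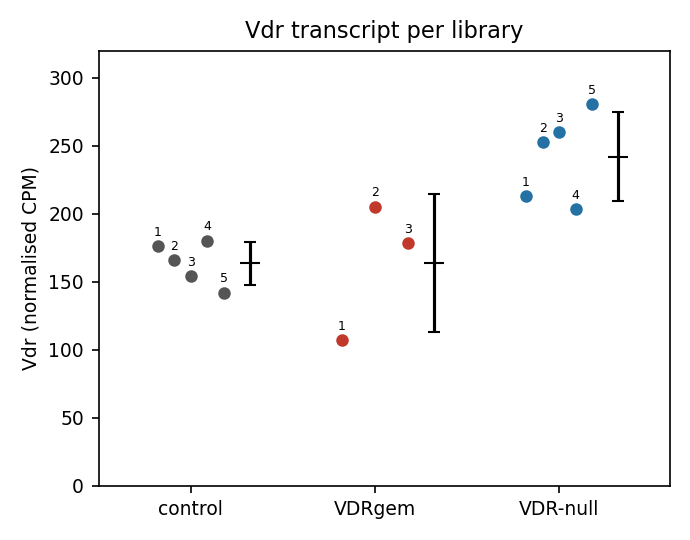
Vdr level in normalised counts (CPM) for each library, with replicate numbers above the points and the group mean ± SD beside them. The VDR-null libraries lie between 204 and 281 CPM, above every control, and the VDRgem libraries lie between 107 and 205 CPM.

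The comparison of VDRgem with control asks which transcripts of the incisor differ when the receptor cannot answer its natural ligand. Transcripts of dividing cells, of dental papilla and of Hedgehog and FGF response genes were lower in VDRgem, and transcripts of collagen-rich matrix, dental follicle, immediate early genes and oral keratinocytes were higher. These are list calls of camera at its preset correlation, with adjusted p of 0.151 to 0.195 with an estimated correlation, and for FGF response 4 of 13 members passed. Aurka, a kinase of mitosis, stood at 7.25 ± 0.575 CPM in VDRgem (SD, n = 3) against 17.4 ± 1.44 CPM in control (n = 5), and Sfrp5, a secreted Wnt antagonist, at 1.09 ± 0.283 against 13.6 ± 2.54 CPM. Scx, a transcription factor of tendon and ligament cells, stood at 3.66 ± 1.25 against 1.40 ± 0.256 CPM, and Col3a1, a fibrillar collagen, at 19920 ± 2660 against 11020 ± 1230 CPM. The keratin Krt10, made by differentiating keratinocytes, differed widely among the mutants, at 1963, 812 and 14.1 CPM in VDRgem 1, 2 and 3 against 4.05 to 6.96 CPM in controls.

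Of 17837 genes tested with edgeR's quasi-likelihood test, 1537 passed a Benjamini-Hochberg adjusted p of 0.05, of which 856 were higher and 681 lower in VDRgem. The median absolute log2 fold change of these genes was 0.91. The selection stated with the series is a p under 0.05 and an absolute log2 fold change over 0.3, and it names no adjustment. Read here as an unadjusted p, it took 3385 genes, 1808 higher and 1577 lower. Scaling by library totals alone called 589 higher and 1576 lower, because it moved the median of all genes by -0.169 on the log2 scale, and fold changes here are relative to the TMM scaling. The count fell to 66 without VDRgem 1 and to 5 without VDRgem 1 and 2, and was 816, 822, 1016, 833 and 643 without control 1, 2, 3, 4 and 5. With the keratinocyte score as a covariate edgeR called 0 genes, with 2507 at an unadjusted p under 0.05. That score was 3.53 to 9.11 in VDRgem and 0.16 to 3.95 in control, so the covariate also takes up part of the group difference. The fit therefore does not show what caused the calls. Of the 82 single VDRgem results taken by the fixed rule, 75 missed the threshold without VDRgem 1, 22 without VDRgem 2 and 15 without VDRgem 3. Those that passed without VDRgem 1 were Fmo9, Cyp2t4, Krt10, Il1f9, Wnt10b, Etv5 and Krt1. Leaving out control 1, 2, 3, 4 or 5 ended 21, 24, 18, 20 or 25 of these calls. All 82 missed the threshold with 1 surrogate variable, 82 with the keratinocyte covariate and 26 with limma-voom.

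Among 35 gene lists fixed in advance, cell cycle genes gave the smallest camera p in VDRgem. Of 21 measured members 20 fell (21 adjusted over the list alone), with a median log2 fold change of -0.95 and a camera adjusted p of 1.35e-21. With inter-gene correlation estimated from these libraries the list missed the threshold, at adjusted p = 0.151 with an estimated correlation. Aurka fell by 1.26 on the log2 scale (SE 0.24, adjusted p = 0.0118), the replication helicase subunit Mcm5 by 1.06 (SE 0.23, adjusted p = 0.0181) and Rrm2, which supplies deoxynucleotides, by 0.98 (SE 0.22, adjusted p = 0.0184). The list's mean log2 CPM was 4.28, 4.47 and 4.31 in VDRgem 1, 2 and 3 and 5.07 to 5.42 in controls. Without VDRgem 1 the median was -0.91 and 0 members passed in edgeR. Falls numbered 11 and 12 without VDRgem 2 and 3, and 12, 11, 10 and 7 without control 1, 2, 4 and 5.

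Dental papilla and pulp genes fell in 6 of 18 measured members (9 adjusted over the list alone), with a median log2 fold change of -0.50. For the papilla list camera gave an adjusted p of 2.5e-07 (adjusted p = 0.151 with an estimated correlation). Fgf3, a growth factor of the papilla, fell by 3.02 on the log2 scale (SE 0.54, adjusted p = 0.00982), from 2.90 ± 0.587 CPM in control (SD, n = 5) to 0.352 ± 0.142 CPM in VDRgem (n = 3). Lhx6, a homeobox gene of jaw mesenchyme, fell by 0.75 (SE 0.12, adjusted p = 0.0082). Hedgehog response genes fell in 5 of 10 members and rose in 1 (5 and 2 adjusted over the list alone), with a median of -0.76. For the Hedgehog list camera gave an adjusted p of 0.0268 (adjusted p = 0.195 with an estimated correlation). The Hedgehog transcription factor Gli1 fell by 1.39 (SE 0.27, adjusted p = 0.0122) and the receptor Ptch1 by 1.49 (SE 0.28, adjusted p = 0.0107), while the co-receptor Boc rose by 0.65 (SE 0.15, adjusted p = 0.0194). Shh and Hhip, named after their values were seen, were also among the members that fell. Without VDRgem 2 or VDRgem 3 the Hedgehog list missed the threshold, at camera adjusted p = 0.0661 and 0.115. It also did so with the keratinocyte covariate (camera adjusted p = 0.129). FGF response genes fell in 4 of 13 members (4 adjusted over the list alone), with a median of -0.12. For the FGF list camera gave an adjusted p of 0.00304 (adjusted p = 0.194 with an estimated correlation). These were Fgf3, Fgf10 and the FGF-induced transcription factors Etv4, at -1.74 (SE 0.36, adjusted p = 0.0151), and Etv5, at -0.84 (SE 0.15, adjusted p = 0.00982). Among all genes eligible by size, the falls of Sfrp5 (-3.63, SE 0.58), the calmodulin-binding Pcp4 (-4.35, SE 0.83), the retinoic acid-degrading enzyme Cyp26c1 (-3.50, SE 0.69) and Lypd1 (-3.27, SE 0.72) were among the 8 largest, with Atp6v1b1, Fcrl6, Cldn6 and Trpm1 the others. Of these 8 falls, 1, 8, 7, 0 and 4 lay below every control in VDR-null 1, 2, 3, 4 and 5. Leaving out VDRgem 1 left 0 papilla and 0 Hedgehog members past the threshold in edgeR, with medians of -0.57 and -0.62, and 1 FGF member, with a median of -0.31. Hedgehog falls numbered 2 without VDRgem 2 and 3, 3 and 2 without control 2, 3 and 5, and the FGF median was -0.07 without control 4.

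Genes of collagen and fibrous matrix rose in 8 of 20 members (13 adjusted over the list alone), with a median log2 fold change of 0.46. For the collagen list camera gave an adjusted p of 7.28e-10 (adjusted p = 0.151 with an estimated correlation). Col3a1 rose by 0.85 (SE 0.17, adjusted p = 0.0138), the elastic fibre protein Eln by 1.09 (SE 0.24, adjusted p = 0.0184) and Postn, a matrix protein of the periodontal ligament, by 0.95 (SE 0.20, adjusted p = 0.0151). Dental follicle and periodontal genes rose in 6 of 14 members (10 adjusted over the list alone), with a median of 0.53. For the follicle list camera gave an adjusted p of 1.22e-08 (adjusted p = 0.151 with an estimated correlation). Scx rose by 1.38 (SE 0.25, adjusted p = 0.00982) and the small proteoglycan Aspn by 1.85 (SE 0.40, adjusted p = 0.0178). Matrix proteases and inhibitors rose in 5 of 17 members (8 adjusted over the list alone), with a median of 0.38. For the protease list camera gave an adjusted p of 4.75e-06 (adjusted p = 0.17 with an estimated correlation). The gelatinase Mmp2 rose by 0.54 (SE 0.10, adjusted p = 0.0117), Mmp11 by 0.41 (SE 0.09, adjusted p = 0.0151) and the membrane-bound Mmp14 by 0.42 (SE 0.12, adjusted p = 0.0375), and Mmp12 and Klk4, named after their values were seen, were the others. In the fit without VDRgem 1 the collagen, follicle and protease lists had 0 members past the threshold in edgeR, with medians of 0.41, 0.50 and 0.37. Collagen members numbered 4 without VDRgem 2 and 5, 4, 5, 5 and 3 without control 1 to 5. Protease members numbered 2 without VDRgem 2 and 2, 2, 3, 2 and 2 without control 1 to 5.

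Genes of maturation-stage ameloblasts, the cells that harden enamel, rose in 4 of 19 members (5 adjusted over the list alone), with a median of 0.29. For the maturation list camera gave an adjusted p of 0.00304 (adjusted p = 0.271 with an estimated correlation). Odam, a protein of the maturing enamel surface, rose by 0.90 (SE 0.20, adjusted p = 0.0178), the potassium-dependent sodium and calcium exchanger Slc24a4 by 0.63 (SE 0.18, adjusted p = 0.0454) and Gm17660, an older name of Scpppq1, by 1.57 (SE 0.31, adjusted p = 0.0122), and the enamel protease Klk4 was the other. Secretory ameloblast genes had a median of 0.04 (camera adjusted p = 0.85), and only Sp6 of 17 fell, by 0.53 (SE 0.12, adjusted p = 0.021; 1 rose and 2 fell adjusted over the list alone). Odontoblast and dentin genes had a median of 0.16, a mean of -0.02 and a camera adjusted p of 0.918, and Lef1, a Wnt transcription factor, was the only 1 of 20 to fall, by 0.72 (SE 0.17, adjusted p = 0.0211; 2 rose and 2 fell adjusted over the list alone). Osteoclast genes rose in 1 of 15 members (1 adjusted over the list alone), the integrin Itgb3, at 0.74 (SE 0.18, adjusted p = 0.0252), with all 15 positive and a median of 0.48. For the osteoclast list camera gave an adjusted p of 0.0042 (adjusted p = 0.522 with an estimated correlation). Without VDRgem 1 or VDRgem 3 this list missed the threshold, at camera adjusted p = 0.0703 and 0.0574. Osteoblast and osteocyte genes had a median of 0.24 and a camera adjusted p of 0.0235 (adjusted p = 0.522 with an estimated correlation). None of the 16 osteoblast members passed in edgeR over all genes, 2 rose adjusted over the list alone, and the camera adjusted p was 0.231 without VDRgem 3 and 0.0715 without control 5. The maturation list had 0 members past the threshold in edgeR and a median of 0.15 without VDRgem 1, and 2 members without VDRgem 2, VDR-null 5 or control 1, 3, 4 or 5. The osteoclast list had 0 members and a median of 0.18 without VDRgem 1, 0 members without control 2 or 5 and 2 without VDR-null 1. In the osteoblast list 1 member passed without VDR-null 1, 2 or 3.

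Oral and gingival keratinocyte genes, a list included because a dissected incisor can carry gum epithelium, rose in 13 of 14 members (14 adjusted over the list alone). Their median log2 fold change was 5.20 with a camera adjusted p of 1.54e-14 (adjusted p = 0.151 with an estimated correlation). The list's mean log2 CPM was 9.11, 6.96 and 3.53 in VDRgem 1, 2 and 3, 0.16 to 3.95 in controls and -0.13 to 1.79 in VDR-null. Krt10 rose by 7.50 (SE 0.92, adjusted p = 0.0041) and Krt1, its partner keratin, by 8.13 (SE 1.25, adjusted p = 0.0076), and without VDRgem 1 they still rose, while the list median fell to 3.12 and 2 members passed. Idi2 and the wound keratins Krt6b and Krt16, among the 8 largest rises of all genes, followed the same libraries, with Krt6b at 206, 125 and 8.73 CPM in VDRgem 1, 2 and 3. Immediate early and heat shock genes, which respond within minutes to stress and handling, rose in 8 of 15 members (14 adjusted over the list alone), with a median of 1.17. For the stress-response list camera gave an adjusted p of 5.75e-12 (adjusted p = 0.151 with an estimated correlation). Egr1 rose by 2.48 (SE 0.43, adjusted p = 0.00982), Fos by 2.03 (SE 0.36, adjusted p = 0.00982) and Hspa1a by 1.74 (SE 0.32, adjusted p = 0.0106). The mean log2 CPM of this list was 5.12, 4.49 and 3.70 in VDRgem 1, 2 and 3 and 3.39 ± 0.162 in controls (SD, n = 5), so among the VDRgem libraries it had the order of the keratinocyte list. Without VDRgem 1 its median was 0.74 and 0 immediate early members passed in edgeR, and without VDRgem 3 13 did. The immediate early list was not called with the keratinocyte covariate (camera adjusted p = 0.154).

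**Figure D2:**
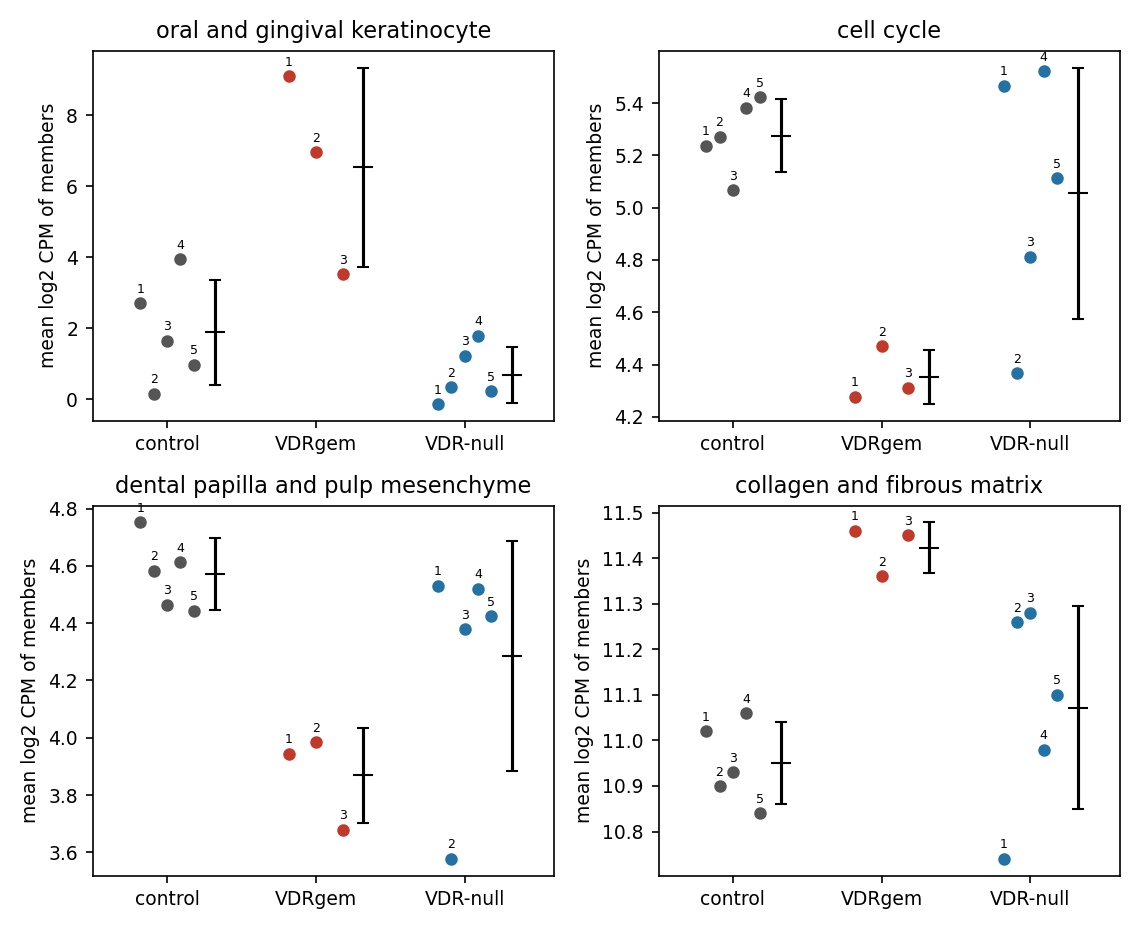
Mean log2 CPM of the measured members of 4 fixed lists for each library, with replicate numbers above the points and the group mean ± SD beside them. Keratinocyte transcripts range from 3.53 to 9.11 among the VDRgem libraries, and the VDRgem cell cycle values of 4.28 to 4.47 lie below every control and around the 4.37 of VDR-null 2.

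Markers of other tissues moved less evenly. Skeletal muscle genes had a median of 2.52 and a camera adjusted p of 0.00304 (adjusted p = 0.522 with an estimated correlation), with 1 of 15 risen, the embryonic myosin Myh3 at 5.63 (SE 1.64, adjusted p = 0.0485), and 0 adjusted over the list alone in edgeR. Their mean log2 CPM was 3.36 in VDRgem 1, the library with the highest keratinocyte level, and 1.55 and 1.18 in VDRgem 2 and 3. Adipocyte genes, of which only 3 were measured, rose in 2 (2 adjusted over the list alone), the fatty acid carrier Fabp4 at 1.56 (SE 0.39, adjusted p = 0.0277) and the lipase Lpl at 0.91 (SE 0.18, adjusted p = 0.0122), with a camera adjusted p of 0.00312 (adjusted p = 0.151 with an estimated correlation). Smooth muscle and pericyte genes rose in 2 of 11 members (2 adjusted over the list alone), Myh11 at 0.87 and the receptor Notch3 at 0.49, with a median of 0.25. For the smooth muscle list camera gave an adjusted p of 0.00403 (adjusted p = 0.17 with an estimated correlation). Endothelial genes rose in 2 of 12 members (3 adjusted over the list alone), Pecam1 at 0.39 and Eng at 0.31, with a median of 0.20. For the endothelial list camera gave an adjusted p of 0.00312 (adjusted p = 0.461 with an estimated correlation). Macrophage genes had a median of 0.25 and a camera adjusted p of 0.00605 (adjusted p = 0.522 with an estimated correlation), and Schwann cell genes a median of 0.47 and a camera adjusted p of 0.0155 (adjusted p = 0.537 with an estimated correlation). None of the 14 macrophage members and 1 of the 12 Schwann cell members, the growth factor co-receptor Gfra3 at 0.70, passed in edgeR, with 0 and 1 adjusted over the list alone. Without VDRgem 3 the smooth muscle, endothelial, macrophage and Schwann cell lists missed the threshold, at camera adjusted p = 0.0879, 0.165, 0.5 and 0.224. The fit without VDRgem 1 left 0 members of the muscle, adipocyte, smooth muscle, endothelial and Schwann cell lists past the threshold in edgeR, with a muscle median of 1.35. Leaving out control 1, 2, 3 or 5 left at most 1 in each list, and leaving out control 4 at most 1 except for 2 adipocyte members. Muscle members numbered 2, 4 and 0 without VDRgem 3, VDR-null 3 and VDR-null 4, and 2 Schwann cell members passed without VDR-null 5. The fit without VDRgem 3 had medians of 0.12, 0.10 and 0.21 for endothelial, macrophage and Schwann cell genes, with 0 endothelial, 1 smooth muscle and 0 Schwann cell members. Smooth muscle had 1 member without VDRgem 2, VDR-null 2 or VDR-null 4, and endothelium 1 without VDRgem 2, VDR-null 4 or VDR-null 5. Eng was at 0.23 with the GC offset (edgeR adjusted p = 0.0781).

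Cholesterol synthesis genes fell in 2 of 17 members (7 adjusted over the list alone), among them the feedback regulator Insig1 at -0.83 (SE 0.20, adjusted p = 0.024), with all 17 negative and a median of -0.38. For the cholesterol list camera gave an adjusted p of 0.000107 (adjusted p = 0.461 with an estimated correlation). Circadian clock genes rose in 4 of 15 members (4 adjusted over the list alone), with a median of 0.26. For the clock list camera gave an adjusted p of 0.00352 (adjusted p = 0.461 with an estimated correlation). The repressor Nr1d1 rose by 1.10 (SE 0.26, adjusted p = 0.0222), its target Arntl by 0.48 (SE 0.12, adjusted p = 0.0275) and Per1 by 0.49 (SE 0.14, adjusted p = 0.0471), and Npas2, named after its value was seen, was the other. In the fits without VDRgem 1 and without VDRgem 2, 0 cholesterol members passed in edgeR, and 0 and 2 clock members. Cholesterol falls numbered 1 without each of control 1 to 5, VDRgem 3, VDR-null 1 or VDR-null 5 and 5 without VDR-null 2. Clock rises numbered 0 without control 1, 2, 4 or 5 and 2 without control 3 or VDR-null 4. Per1 was at 0.37 with the GC offset (edgeR adjusted p = 0.0592).

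Vitamin D target genes were not called as a list in VDRgem, with a median of 0.17 and a camera adjusted p of 0.232. Cyp24a1, the enzyme that degrades active vitamin D and a direct target of the receptor, was the only 1 of 16 measured members to pass (1 adjusted over the list alone). It fell by 1.43 on the log2 scale (SE 0.39, adjusted p = 0.0364), from 0.404 ± 0.0904 CPM in control (SD, n = 5) to 0.152 ± 0.041 CPM in VDRgem (n = 3), and it missed the threshold when any single control or VDRgem library was left out, with adjusted p from 0.0506 to 0.117. The list of vitamin D transport, metabolism and receptor genes had a median of -0.00 and a camera adjusted p of 0.844, with Cyp24a1 again the only member to pass (1 adjusted over the list alone). Mineral regulation genes had a median of 0.14 and a camera adjusted p of 0.144, and the parathyroid hormone receptor Pth1r, at 0.52 (SE 0.14, adjusted p = 0.0376), was the only 1 of 16 to rise (3 adjusted over the list alone). Wnt response genes rose in 2 and fell in 3 of 14 (2 and 3 adjusted over the list alone), with a median of 0.08 against a downward camera direction at an adjusted p of 0.887. The ligand Wnt10b rose by 1.14 (SE 0.18, adjusted p = 0.0076), while the feedback gene Axin2 fell by 0.60 (SE 0.11, adjusted p = 0.0105) and Tcf7 by 1.03 (SE 0.21, adjusted p = 0.0142), with Lef1 among the falls and Dkk2, named after its value was seen, among the rises. Dental epithelial stem cell genes rose in 4 and fell in 4 of 20 (4 and 4 adjusted over the list alone), with a median of 0.23 and a camera adjusted p of 0.844, the falls being Sfrp5, Ptch1, Gli1 and Shh. The rises were the basal keratin Krt15 at 3.14 (SE 0.58, adjusted p = 0.0107) and, named after their values were seen, Krt5, Krt14 and Sox2. The level of this list, at 5.97, 5.40 and 5.17 in VDRgem 1, 2 and 3, had the order of the keratinocyte list, at 9.11, 6.96 and 3.53. Hypoxia and glycolysis genes had a camera adjusted p of 0.377 with Slc2a1 and Egln3 risen and Hk2 fallen (2 and 1 adjusted over the list alone). Cartilage genes had 0.548 with Acan risen and Sox9 fallen (1 and 1 adjusted over the list alone), and BMP response genes, with a median of 0.06 against a downward camera direction, 0.77 with Smad9 fallen (3 adjusted over the list alone). The remaining lists were not called and had no member past the threshold, with camera adjusted p of 0.179 for unfolded protein response, 0.144 for interferon response, 0.377 for erythroid, 0.267 for neutrophil and marrow and 0.283 for lymphocyte genes, of which fry called the lymphocyte list, at adjusted p = 0.0242.

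**Figure D3:**
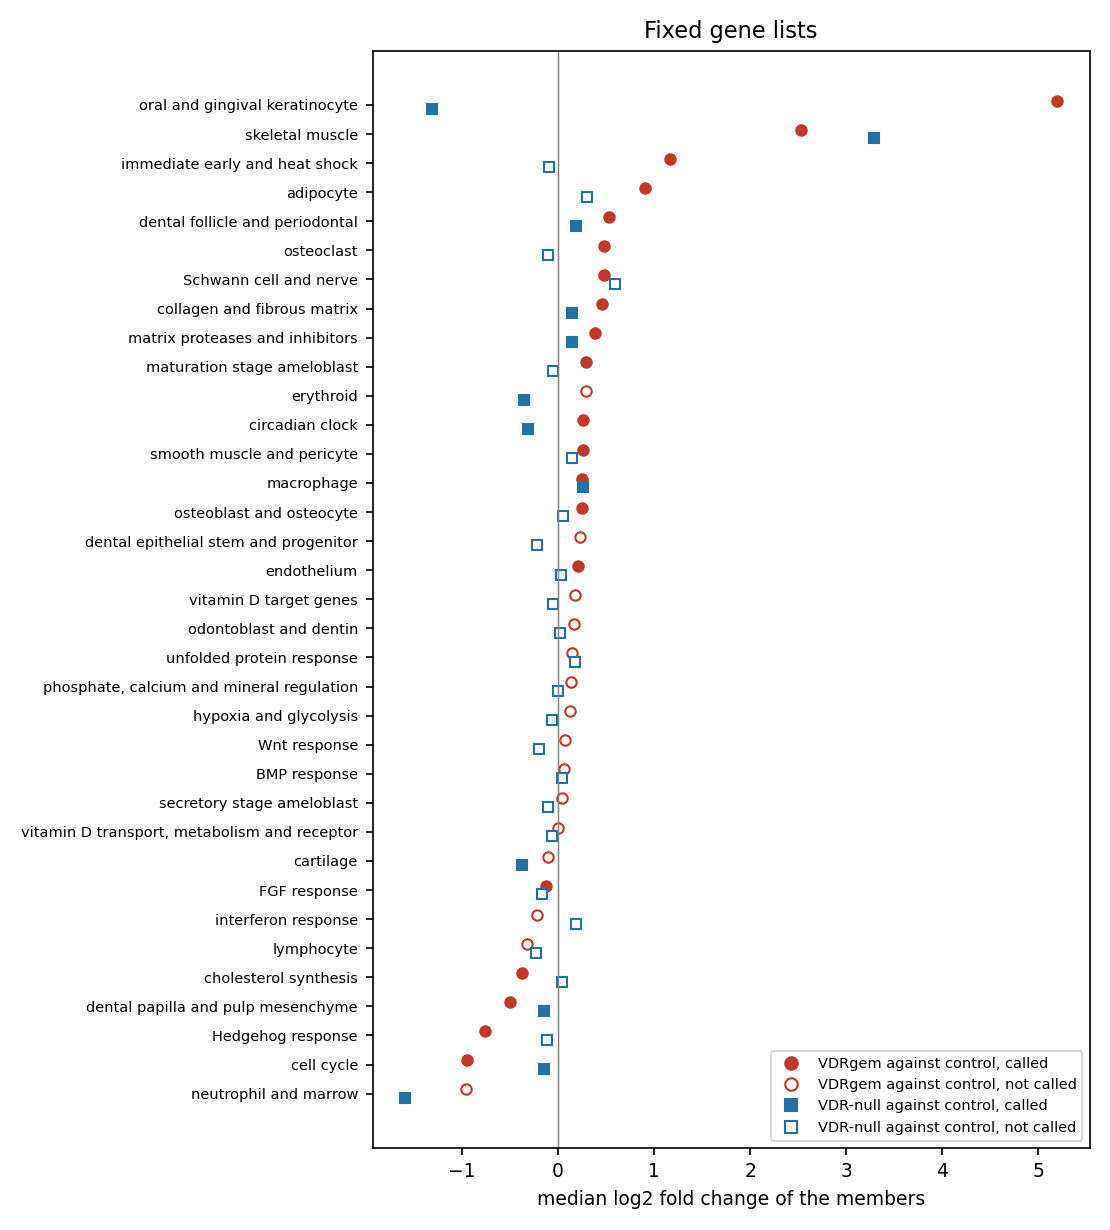
Median log2 fold change of the measured members of the 35 fixed lists in VDRgem (circles) and VDR-null (squares), each against control, with filled symbols where camera called the list at its preset correlation. The VDRgem medians run from -0.96 for neutrophil and marrow to 5.20 for keratinocyte genes, and no list is called in either comparison when the correlation is estimated.

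The comparison of VDR-null with control asks which incisor transcripts differ in mice labelled as lacking a working receptor. Transcripts on the macrophage list were higher, and those on the neutrophil, circadian and dental papilla lists were lower. In each of these lists 1 member passed, and adjusted p = 0.802 with an estimated correlation for all of them. Cd163, a haemoglobin scavenger receptor of tissue macrophages, stood at 3.96 ± 0.776 CPM in VDR-null (SD, n = 5) against 1.31 ± 0.285 CPM in control (n = 5), and the macrophage marker Adgre1 at 24.6 ± 3.44 against 14.5 ± 1.20 CPM. Dlx5, a homeobox gene of jaw and tooth mesenchyme, stood at 41.8 ± 8.51 against 64.5 ± 6.71 CPM, and Phospho1, a phosphatase that starts mineral formation, at 0.214 ± 0.111 against 0.560 ± 0.176 CPM. Several processed copies of ribosomal protein genes were higher, with Rpl10-ps3 at 8.60 ± 1.13 against 3.54 ± 0.482 CPM.

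In VDR-null 238 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 121 higher and 117 lower, with a median absolute log2 fold change of 0.56. The selection stated with the series took 2349 genes, 960 higher and 1389 lower. Upper-quartile scaling called 147 higher and 301 lower, and scaling by library totals alone 91 higher and 256 lower. Fold changes followed the GC content of the transcript, with a Spearman rho of -0.61 across 12967 genes, which are not independent replicates. Transcripts with a GC content up to 40% had a median log2 fold change of 0.19 and those over 60% a median of -0.37. With a GC trend per library as an offset, chosen after this trend was seen, 30 genes passed, and 26 of them were among the 238. Leaving out control 1, 2, 3 or 4 left 7, 6, 8 or 9 calls, and leaving out VDR-null 1, 2, 3, 4 or 5 gave 31, 10, 498, 450 or 155. The VDRgem libraries enter this comparison only through the shared spread, the gene filter and the scaling. Leaving out VDRgem 1, 2 or 3 gave 680, 42 or 685. The order of the counts of the mutants, 1537 and 238, turned without VDRgem 1 (66 and 680), without VDRgem 1 and 2 (5 and 676), with 1 surrogate variable (13 and 2142) and with the keratinocyte covariate (0 in edgeR and 42).

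**Figure D4:**
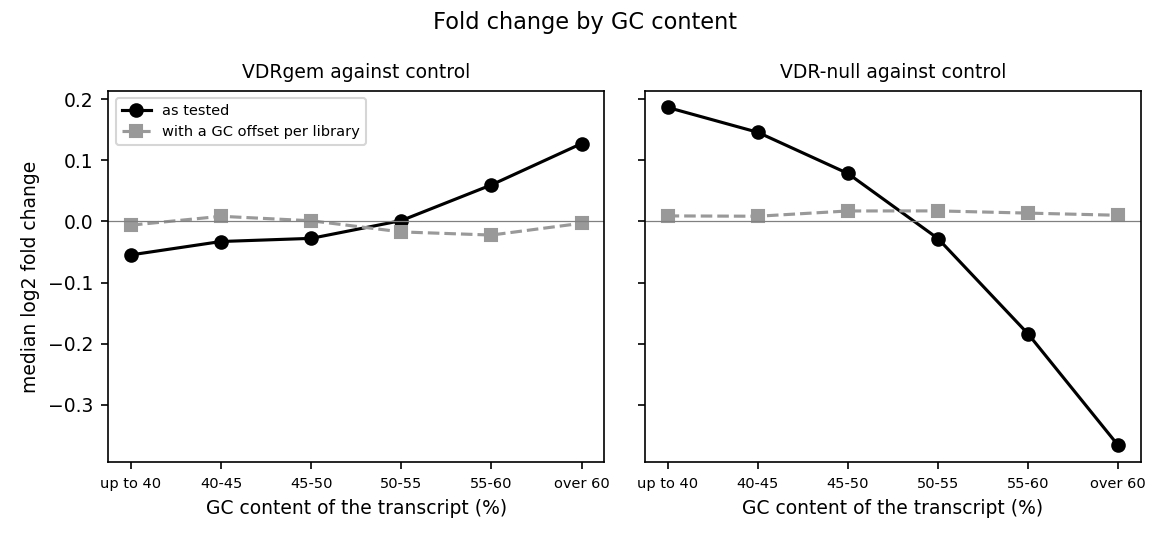
Median log2 fold change of genes grouped by the GC content of their transcripts, for VDRgem and VDR-null against control, as tested (circles) and with a GC trend per library as an offset (squares). In VDR-null the medians run from 0.19 up to 40% GC to -0.37 over 60% GC as tested, and the VDRgem medians from -0.05 to 0.13.

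Macrophage genes rose in 1 of 14 members (6 adjusted over the list alone), with 13 positive and a median log2 fold change of 0.26. For the macrophage list camera gave an adjusted p of 0.000485 (adjusted p = 0.802 with an estimated correlation). Adgre1 rose by 0.76 (SE 0.15, adjusted p = 0.0373), and Cd163, outside the list, by 1.59 (SE 0.27, adjusted p = 0.0231). With the GC offset Cd163 still passed, at 1.54, and Adgre1, at 0.69, did not (edgeR adjusted p = 0.066). Cd163 missed the threshold without control 1, 2, 3 or 4 and without VDR-null 2. Macrophage rises numbered 0 without control 1, 2, 3 or 4, VDRgem 2 and VDR-null 1 or 2 in edgeR, and 4 and 5 without VDRgem 1 and 3, with a median of 0.14 without VDR-null 2. Neutrophil and marrow genes fell in 1 of 8 members (7 adjusted over the list alone), with all 8 negative and a median of -1.59. Their mean log2 CPM was low and overlapped, from -1.34 to 1.28 in controls and from -2.17 to -0.55 in VDR-null. Control 1, at -1.34, lay below every VDR-null library except VDR-null 5. For the neutrophil list camera gave an adjusted p of 0.000142 (adjusted p = 0.802 with an estimated correlation). The granule protease Prtn3 fell by 1.15 (SE 0.24, adjusted p = 0.0411), and S100a8 and Camp had log2 fold changes of -1.26 (SE 0.39, adjusted p = 0.0889) and -2.32 (SE 0.68, adjusted p = 0.0781). Prtn3 missed the threshold with the GC offset, at -0.80 (edgeR adjusted p = 0.125), and without each of control 1 to 5, VDRgem 2 and VDR-null 1, 2 or 5. Erythroid genes had a median of -0.36 and a camera adjusted p of 0.033 (adjusted p = 0.802 with an estimated correlation), with 0 of 10 passing in edgeR and 0 adjusted over the list alone. The erythroid list missed the threshold without control 2 or 5 (0.054 and 0.0606) and without VDR-null 4 or 5 (0.174 and 0.0827), with medians of -0.63, -0.56 and -0.17 without VDR-null 2, 3 and 4. Lymphocyte genes, with a camera adjusted p of 0.0767, were the only list called by fry, at adjusted p = 0.00561.

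Circadian clock genes fell in 1 of 15 members (5 adjusted over the list alone), with a median of -0.31. For the clock list camera gave an adjusted p of 0.0154 (adjusted p = 0.802 with an estimated correlation). Per1 fell by 0.59 (SE 0.12, adjusted p = 0.0412), and the clock output genes Ciart and Dbp had values of -0.62 (SE 0.18, adjusted p = 0.0797) and -0.55 (SE 0.16, adjusted p = 0.0761). Without VDR-null 3 the clock list had a camera adjusted p of 0.0935. Dental papilla genes fell in 1 of 18 members (3 adjusted over the list alone), Dlx5 at -0.63 (SE 0.13, adjusted p = 0.042), with a median of -0.15. For the papilla list camera gave an adjusted p of 0.033 (adjusted p = 0.802 with an estimated correlation). Cell cycle genes had a median of -0.15 and a camera adjusted p of 0.033 (adjusted p = 0.802 with an estimated correlation), with 0 of 21 passing in edgeR and 0 adjusted over the list alone. Without VDR-null 2, whose cell cycle and papilla levels of 4.37 and 3.58 were the lowest of its group, these lists had camera adjusted p of 0.244 for papilla and 0.524 for cell cycle. The papilla list also missed the threshold without VDR-null 3 (0.0626) and control 1 or 2 (0.0713 and 0.054), and the cell cycle list without VDR-null 3 (0.189) and control 5 (0.0919). The papilla and follicle lists had camera adjusted p of 0.0664 and 0.151 with the GC offset. The other 10 lists stayed called with it, with cell cycle at 0.000433 and collagen at 0.00252, and the Schwann cell, unfolded protein response and lymphocyte lists were called only with it (0.00252, 0.0175 and 0.0457), making 13 at the preset correlation (without the offset the smallest adjusted p = 0.802 with an estimated correlation). Phospho1 fell by 1.48 (SE 0.34, adjusted p = 0.049) and was the only member to pass of both the odontoblast list (camera adjusted p = 0.611) and the mineral regulation list (also 0.611), with 1 adjusted over the list alone in each. Collagen and matrix genes had a median of 0.15 and a camera adjusted p of 0.037 (adjusted p = 0.802 with an estimated correlation), and dental follicle genes a median of 0.18 and a camera adjusted p of 0.0434 (adjusted p = 0.802 with an estimated correlation). The proteoglycan Dcn, at 0.47 (SE 0.10, adjusted p = 0.0402), was the only member of either to rise (2 rose and 4 rose and 1 fell adjusted over the list alone). Matrix proteases had a median of 0.14 and a camera adjusted p of 0.033 (adjusted p = 0.802 with an estimated correlation), with 0 of 17 passing in edgeR and 1 adjusted over the list alone. Without VDR-null 2 the collagen, follicle and protease lists had camera adjusted p of 0.171, 0.261 and 0.206. The collagen list also missed the threshold without VDR-null 3 or 5 (0.18 and 0.0702) and control 2 or 5 (0.0631 and 0.123), and the protease list without VDR-null 3 (0.133) and control 2 or 5 (0.054 and 0.08). The follicle list did so without VDR-null 4 (0.0669), VDRgem 3 (0.052) and control 1, 2 or 5 (0.054, 0.0589 and 0.0919). Per1 with the GC offset was at -0.31 (edgeR adjusted p = 0.164), Dlx5 at -0.52 (0.0742), Phospho1 at -1.15 (0.0896) and Dcn at 0.29 (0.305), and none of the 4 passed. All also missed the threshold without control 1, 2, 3 or 4, VDRgem 2 and VDR-null 1, 2 or 5, and Phospho1, Per1 and Dcn without control 5 as well, as did Phospho1 without VDR-null 4. Papilla medians were -0.09 without control 1 and -0.23 without control 3, VDR-null 1 or VDR-null 4, and clock medians -0.19 without control 3, -0.15 without VDR-null 3 and -0.16 with the GC offset. Cell cycle medians were -0.27, -0.03, -0.09 and -0.24 without VDR-null 1, 2, 3 and 4. The follicle median was 0.05 without VDR-null 2, protease medians 0.07 and 0.22 without VDR-null 2 and 4, and collagen medians 0.23 without VDR-null 1 and 0.09 without control 3 or VDR-null 5.

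Keratinocyte genes were lower, with a median of -1.31 and a camera adjusted p of 0.033 (adjusted p = 0.802 with an estimated correlation). None of the 14 passed in edgeR over all genes and 4 fell adjusted over the list alone. Cartilage genes had a median of -0.38 and a camera adjusted p of 0.0312 (adjusted p = 0.802 with an estimated correlation), with 0 of 12 passing and 0 adjusted over the list alone. Skeletal muscle genes had a median of 3.28 and a camera adjusted p of 0.033 (adjusted p = 0.802 with an estimated correlation), with 0 of 15 passing in edgeR and 10 risen adjusted over the list alone. Their mean log2 CPM was 4.98 in VDR-null 3 and -1.70 to 1.71 in the other VDR-null libraries, and without VDR-null 3 the camera adjusted p was 0.615. The muscle median was then 0.70, and the keratinocyte median was -0.54 without control 4, and the cartilage median was -0.21 with the GC offset. The muscle list also missed the threshold without control 1, 2 or 5 (0.054, 0.054 and 0.0606), and the keratinocyte list without control 1 or 4 (0.054 and 0.127) and VDR-null 2, 3 or 5 (0.0788, 0.0626 and 0.0729). Vitamin D target genes had a median of -0.06 against an upward camera direction at an adjusted p of 0.985, with 0 of 16 passing in edgeR and 0 adjusted over the list alone, and Cyp24a1 stood at 0.306 ± 0.133 CPM (SD, n = 5). At an unadjusted p under 0.05 the edgeR test had 4068 of all genes and DESeq2 called 1657 after adjustment.

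Among the genes picked by size of change, the rises after Cd163 were processed copies of abundant genes, such as Rpl31-ps8 at 1.31 (SE 0.17, adjusted p = 0.00697) and Rpl10-ps3 at 1.28 (SE 0.15, adjusted p = 0.00695). Reads from such copies and from the parent genes are nearly identical, so their counts are uncertain. Of the 32 single VDR-null results taken by the rule, 29 missed the threshold without each of control 1 to 4, 28 without VDR-null 2, 22 without VDR-null 1, 18 without VDRgem 2, 10 without VDR-null 5, 9 without control 5, 1 without VDR-null 4, 22 with the GC offset and 22 with the keratinocyte covariate. The 8 falls were Prr7 at -1.84 (SE 0.35, adjusted p = 0.0346), C1qtnf4 at -1.77 (SE 0.37, adjusted p = 0.0406), the cytochrome oxidase assembly gene Cox16 at -1.66 (SE 0.22, adjusted p = 0.00697), Rpl36 at -1.60 (SE 0.25, adjusted p = 0.018), Ntn5 at -1.26 (SE 0.24, adjusted p = 0.0346), Hs3st6 at -1.21 (SE 0.27, adjusted p = 0.0458), the mitochondrial pyruvate carrier Mpc1 at -1.18 (SE 0.23, adjusted p = 0.0381) and the linker histone H1fx at -1.15 (SE 0.22, adjusted p = 0.034). With the GC offset Cox16 and Rpl36 still passed, at -1.84 and -1.22, and H1fx, at -0.28, Prr7, at -1.07, C1qtnf4, at -0.94, Ntn5, at -0.79, Hs3st6, at -0.79, and Mpc1, at -1.23, did not (edgeR adjusted p from 0.054 for Mpc1 to 0.343 for H1fx).

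The direct comparison of the mutants tests which transcripts differ between mice whose receptor ignores its hormone and mice labelled VDR-null. VDRgem incisors had lower cell cycle, papilla, cholesterol and interferon transcripts than VDR-null incisors, and higher keratinocyte, immediate early, clock, enamel maturation and osteoclast transcripts. These are list calls at the preset correlation, each with adjusted p = 0.52 with an estimated correlation, and 5 of 15 members passed in the interferon and in the osteoclast list. Scx stood at 3.66 ± 1.25 CPM in VDRgem (SD, n = 3) against 0.702 ± 0.153 CPM in VDR-null (n = 5), and Wnt10b at 41.3 ± 12.0 against 16.8 ± 3.35 CPM. Spp1, the matrix phosphoprotein osteopontin and a vitamin D target, stood at 436 ± 106 against 185 ± 52.1 CPM. Fgf3 stood at 0.352 ± 0.142 against 2.17 ± 1.33 CPM, and 1 VDR-null library, VDR-null 2, was close to the VDRgem level at 0.573 CPM.

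In this comparison 3346 genes passed in edgeR's quasi-likelihood test, 1887 higher and 1459 lower in VDRgem, and the selection stated with the series took 4908. Scaling by library totals alone, which moved the median of all genes by -0.164, called 1310 higher and 3616 lower. GC content was related to these fold changes in the opposite sense, with a Spearman rho of 0.53 across 12967 genes, and with the GC offset 2221 genes passed, 1721 of them among the 3346. The count was 434 without VDRgem 1, 1712 without VDRgem 2, 2045 without VDR-null 1, 32 without VDRgem 1 and 2, 753 when the controls were left out of the fit and 13 with the keratinocyte score as a covariate. The keratinocyte score did not overlap between the mutants, so that covariate also takes up part of their difference. Of the 92 single results of this comparison, 58 missed the threshold without VDRgem 1, 25 without VDRgem 2, and between 3 and 19 without any other library. Of these calls 26 were lost with the GC offset, 52 with 1 surrogate variable, 48 with only the groups compared, 13 with limma-voom and 86 without VDRgem 1 and 2, and 4 of the 92 were kept with the keratinocyte covariate.

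Cell cycle genes fell in 16 of 21 members (20 adjusted over the list alone), with a median of -0.78. For the cell cycle list camera gave an adjusted p of 1.23e-09 (adjusted p = 0.52 with an estimated correlation). They included Aurka at -1.10 (SE 0.24, adjusted p = 0.0103). Cell cycle falls numbered 0 (edgeR), 7 and 10 without VDRgem 1, 2 and 3 and 9 and 10 without VDR-null 1 and 4. Dental papilla genes fell in 7 and rose in 1 of 18 (7 and 1 adjusted over the list alone), with a median of -0.29. For the papilla list camera gave an adjusted p of 0.0125 (adjusted p = 0.52 with an estimated correlation). They included Lhx6 at -0.73 (SE 0.12, adjusted p = 0.00335), and the rise was Dlx2, named after its value was seen, as were Tie1, Egfl7 and Tnmd below. Without VDRgem 3 the papilla list had a camera adjusted p of 0.129. Papilla falls numbered 1, 3 and 3 without VDRgem 1, 2 and 3, and 4 without VDR-null 1, 4 or 5 or control 1, 2, 3 or 4. Cholesterol synthesis genes fell in 7 of 17 members (9 adjusted over the list alone), with a median of -0.49. For the cholesterol list camera gave an adjusted p of 0.000615 (adjusted p = 0.52 with an estimated correlation). Cholesterol falls numbered 0 (edgeR), 1 and 2 without VDRgem 1, 2 and 3 and 4, 3 and 4 without VDR-null 1, 4 and 5. Interferon response genes fell in 5 of 15 members (5 adjusted over the list alone), with all 15 negative and a median of -0.38. For the interferon list camera gave an adjusted p of 0.0124 (adjusted p = 0.52 with an estimated correlation). Among them were Oasl2 at -0.66 (SE 0.17, adjusted p = 0.018), Ifit2 at -0.57 (SE 0.14, adjusted p = 0.0175) and, named after their values were seen, Oas1a and Stat2. Interferon falls numbered 0 (edgeR) and 2 without VDRgem 1 and 2, and 3 with the GC offset, where Ifit2 was at -0.38 (edgeR adjusted p = 0.0712).

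Immediate early genes rose in 14 of 15 members (14 adjusted over the list alone), with a median of 1.29. For the stress-response list camera gave an adjusted p of 3.32e-10 (adjusted p = 0.52 with an estimated correlation). They included Junb at 2.58 (SE 0.42, adjusted p = 0.00305). Immediate early rises numbered 5 without VDRgem 1, with a median of 0.67, and 9 without VDR-null 1. Keratinocyte genes rose in all 14 members (14 adjusted over the list alone), with a median of 7.31 and a camera adjusted p of 5.74e-13 (adjusted p = 0.52 with an estimated correlation), and Idi2 stood at 572, 59.0 and 5.21 CPM in VDRgem 1, 2 and 3 against at most 0.0808 CPM in VDR-null. Circadian clock genes rose in 8 of 15 members (8 adjusted over the list alone), with a median of 0.46. For the clock list camera gave an adjusted p of 9.45e-06 (adjusted p = 0.52 with an estimated correlation). They included Per1 at 1.08 (SE 0.14, adjusted p = 0.00125) and Nr1d1 at 1.41 (SE 0.26, adjusted p = 0.00515). Enamel maturation genes rose in 9 of 19 members (10 adjusted over the list alone), with a median of 0.69. For the maturation list camera gave an adjusted p of 0.00138 (adjusted p = 0.52 with an estimated correlation). They included Slc24a4 at 0.95 (SE 0.18, adjusted p = 0.00559) and the transferrin receptor Tfrc at 0.98 (SE 0.23, adjusted p = 0.0124). Osteoclast genes rose in 5 of 15 members (7 adjusted over the list alone), with a median of 0.59. For the osteoclast list camera gave an adjusted p of 0.00138 (adjusted p = 0.52 with an estimated correlation). These were the receptor Siglec15 at 1.87 (SE 0.45, adjusted p = 0.0151), Itgb3 at 0.68 (SE 0.18, adjusted p = 0.022), Nfatc1 at 0.55 (SE 0.14, adjusted p = 0.0182) and, named after their values were seen, Acp5 and Mmp9. Without VDRgem 1 there were 3 clock, 2 maturation and, in edgeR, 0 osteoclast rises, with medians of 0.38 for maturation and 0.39 for osteoclast genes. Leaving out VDR-null 5 left 5 maturation and 3 osteoclast rises. The GC offset left 4 clock and 2 osteoclast rises, without Siglec15, at 0.96 (edgeR adjusted p = 0.146), and Mmp9, at 0.61 (0.0704).

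Collagen genes rose in 6 of 20 members (7 adjusted over the list alone), with a median of 0.30. For the collagen list camera gave an adjusted p of 0.00132 (adjusted p = 0.52 with an estimated correlation). They included Col5a1 at 0.89 (SE 0.15, adjusted p = 0.00338). Dental follicle genes rose in 4 of 14 (5 adjusted over the list alone), with a median of 0.31. For the follicle list camera gave an adjusted p of 0.00327 (adjusted p = 0.52 with an estimated correlation). They included Scx at 2.36 (SE 0.25, adjusted p = 0.000202), Pth1r at 0.81 (SE 0.14, adjusted p = 0.00421) and Aspn at 1.47 (SE 0.40, adjusted p = 0.0237), with Tnmd the other. Endothelial genes rose in 4 of 12 (4 adjusted over the list alone), namely Eng, Plvap, Tie1 and Egfl7, with a camera adjusted p of 0.00828, and erythroid genes in 2 of 10 (2 adjusted over the list alone), Hba-a1 and Slc4a1, with a camera adjusted p of 0.0206 (adjusted p = 0.52 with an estimated correlation for both). Without VDRgem 3 the follicle, endothelial and erythroid lists had camera adjusted p of 0.0768, 0.228 and 0.389, and without VDR-null 4 the erythroid list had 0.062. Collagen rises numbered 2 without VDRgem 1, and follicle rises 2 without VDRgem 1 or VDR-null 5 and 7 without VDR-null 2. Endothelial rises numbered 1 and 2 without VDRgem 1 and 2, with a median of 0.12 without VDRgem 3, where the erythroid median was 0.43. Erythroid rises numbered 0 in edgeR without VDRgem 1, 2 or 3 or VDR-null 1, 4 or 5, 1 without each control or VDR-null 2, and 4 without VDR-null 3. The GC offset left 1 endothelial and 0 erythroid rises in edgeR, without Plvap, Egfl7, Hba-a1 and Slc4a1, and camera gave the endothelial list an adjusted p of 0.0573. Vitamin D target genes were not called as a list, with a camera adjusted p of 0.338, and 3 of 16 rose (3 adjusted over the list alone). These were Spp1 at 1.24 (SE 0.31, adjusted p = 0.017), Tnfsf11, the osteoclast-inducing cytokine RANKL, at 0.78 (SE 0.22, adjusted p = 0.0282), and the Wnt co-receptor Lrp5 at 0.45 (SE 0.12, adjusted p = 0.0231). Rxra, the partner receptor of VDR, was higher by 0.49 (SE 0.10, adjusted p = 0.00867). With the GC offset Rxra, at 0.20 (edgeR adjusted p = 0.143), and Lrp5, at 0.28 (0.0833), did not pass. Without VDRgem 1 Rxra, Spp1, Lrp5 and Tnfsf11 did not, without VDRgem 2 Lrp5 and Tnfsf11 did not, and without VDR-null 1 or 4 Tnfsf11 did not, so that 0 (edgeR) and 1 target rose without VDRgem 1 and 2. The skeletal muscle list, not called at a camera adjusted p of 0.653, had a median of -0.75 against an upward camera direction.

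Genes that passed in both mutants were then compared with control. In total 41 genes passed in both comparisons, 15 higher in both, 7 lower in both and 19 in opposite directions. Independent lists of these sizes would share 5.81 higher, 4.47 lower and 10.2 opposite genes. Genes higher in both included Rgs1, a regulator of immune cell migration, at 2.43 (SE 0.41) in VDRgem and 1.75 (SE 0.39) in VDR-null, Cd163 at 1.49 and 1.59, the macrophage receptor Cd200r1 at 1.01 and 1.33, the hyaluronan synthase Has2 at 0.94 and 0.77, the scavenger receptor Cd36 at 0.64 and 0.81, and the lysosomal protease Ctsc at 0.67 and 0.56. Genes lower in both included Fxyd7 at -1.12 in VDRgem and -0.88 in VDR-null, the replication licensing factor Cdt1 at -0.64 and -0.71, Rpap3 at -0.61 and -0.67, the collagen Col26a1 at -0.58 and -0.60, Dlx5 at -0.57 and -0.63, and Cox6b2 at -0.66 and -0.48. Adjusted p of these 12 genes in edgeR ran from 0.00951 to 0.0486, and Col26a1 stood at 132 ± 3.80 CPM in control (SD, n = 5), 88.4 ± 12.3 CPM in VDRgem (n = 3) and 87.1 ± 11.9 CPM in VDR-null (n = 5). With the GC offset Cd163 and Rpap3 passed in VDR-null, and the other 10 had edgeR adjusted p from 0.0702 to 0.393. Some of these 10 kept much of their log2 fold change, with Rgs1 at 1.57, Cd200r1 at 1.18 and Dlx5 at -0.52, while Col26a1 went to -0.25. Of the 19 genes in opposite directions, 7 were copies of ribosomal protein genes by symbol. AC148174.2, Gm10086, Gm10175, Gm10288, Gm11249, Gm15501, Gm33312 and Gm9625 were also annotated as processed pseudogenes. Gm2000, Gm12184, Gm12355 and Per1 were annotated as protein-coding. All 19 but Per1 and Gm9625 were lower in VDRgem and higher in VDR-null. Of all pseudogenes tested 4.75% passed in VDR-null against 1.21% of other genes, and 6.5% against 8.69% in VDRgem. With the GC offset 4 genes passed in both in the same direction and 11 in opposite directions. The count passing in both in the same direction was 0 without control 1, 2, 3 or 4, 13 without control 5, 3 and 5 without VDRgem 1 and 2, and 5, 1, 47 and 12 without VDR-null 1, 2, 4 and 5. The count in opposite directions was 3 without control 1, 2, 3 or 4, 12 and 55 without VDRgem 2 and 3, and 7 and 4 without VDR-null 1 and 2.

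Over all tested genes the log2 fold changes of the mutants had a Pearson r of -0.056 across genes and a covariance of -0.0178. In 40 simulations of unchanged groups against the same controls r averaged 0.438 (range 0.402 to 0.492) and the covariance 0.0394 (range 0.0365 to 0.0473). The observed values lay below these ranges. The simulations drew each gene on its own, with no GC trend and no difference in tissue. Their ranges therefore do not hold for libraries whose genes vary together, and no conclusion is drawn from the gap. When the controls were divided so that each mutant had its own, r over 20 fits averaged -0.0872 (range -0.281 to 0.186), with a mean of 0 genes passing in both in the same direction and 0.55 in opposite directions. In these fits edgeR called a median of 18 genes in VDRgem (0 to 563) and 2 in VDR-null (1 to 74). With 2 controls the VDRgem count was 0 to 24, and with 3 controls 17 to 563. Without VDRgem 1 and 2 r was 0.327 and the covariance 0.0984, with 1 gene passing in both in the same direction.

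Genes near Vdr were examined because a mutant made in a different strain keeps the strain's flanking chromosome. Within 10 Mb of Vdr 28 of 217 tested genes passed in VDRgem, or 12.9% against 8.56% elsewhere, an odds ratio of 1.58 (95% interval 1.02 to 2.37, two-sided Fisher's exact p = 0.0282). The keratin cluster Krt1 belongs to lies on the same chromosome, and without genes whose symbol begins with Krt the odds ratio was 1.13 (p = 0.61), as reported by the same exact test. In VDR-null 5 of the 217 genes passed, an odds ratio of 1.76 (exact p = 0.218), and between the mutants 54 passed, an odds ratio of 1.44 (exact p = 0.0229), or 1.19 without keratins (exact p = 0.315).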

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

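The direct test between the mutants, the counts over other splits and the gap test were planned. All other tests in this part were chosen only after results were seen, the GC offset after the GC trend but before its own outcome. The patterns weighed are hypotheses found and tested on the same libraries.

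Keratinocyte transcripts were high in VDRgem 1 and 2. The mean log2 CPM of the list was 9.11, 6.96 and 3.53 in VDRgem 1, 2 and 3, a range of 5.58 within a group of the same genotype, and the most abundant members were Krt13 at 5786, 857 and 75.4 CPM, Krt4 at 4484, 677 and 93.8 CPM and Krt1 at 2252, 681 and 5.98 CPM. Oral epithelium left on some incisors may account for this, since it brings all its abundant transcripts together and differs from tooth to tooth, and 6 of the 14 members were over 1 CPM in every control while 0 belonged to another list. A keratinocyte change shared by VDRgem teeth stays open, because 4 of the 14 members lay above every control in all 3 VDRgem libraries. With 3 libraries these explanations cannot be told apart for VDRgem 3, and a difference in dissection between the groups was not recorded.

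Small changes in VDR-null followed GC content. GC bias between libraries may account for many of them, since 10.9% of the 238 calls passed with a GC offset per library, the median absolute log2 fold change of the 238 going from 0.56 to 0.33 while the median SE went from 0.11 to 0.10. Of the 212 calls that ended, 195 had a smaller fold change, 142 of these with an unadjusted p over the limit of the fit without the offset, and 69 kept a p within that limit and ended through the adjustment over all genes. On simulated counts with a GC trend the offset brought false calls of VDR-null against control from 22.7% to 6.32%. The trend added there was the same smooth trend that the offset fits. This shows only that the offset removes such a trend, not whether the trend in these libraries is technical. A genotype effect on GC-rich and GC-poor transcripts stays open, because the GC slope per library differed between VDR-null and control (exact permutation p = 0.0159) and no batch or date is given that would part library handling from genotype, so for the GC trend these cannot be told apart.

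Cell cycle transcripts were lower in all 3 VDRgem libraries. Dilution of tooth RNA by RNA of other tissue was argued against, because it would lower all tooth transcripts alike, and the odontoblast list had a median log2 fold change of 0.16 (SD 0.43 over members) against -0.95 for the cell cycle list. Less of the growing apical end in the tissue taken may account for it, since the papilla list had a median of -0.50. The papilla, Hedgehog and FGF lists were called lower as well (camera adjusted p = 0.151, 0.195 and 0.194 with an estimated correlation). The Hedgehog list was not called without VDRgem 2 (0.0661) or VDRgem 3 (0.115). These lists share fallen members, Fgf3 and Fgf10 in papilla and FGF and Gli1 in papilla and Hedgehog, so their calls are not independent. The dental epithelial stem cell list was not lower, with a median of 0.23 (SD 1.52 over members, 4 risen and 4 fallen). Its level, at 5.97, 5.40 and 5.17 in VDRgem 1, 2 and 3, had the order of the keratinocyte list, and the keratins Krt5, Krt14 and Krt15 were among its rises. It does not decide between these explanations because members went both ways. Fewer dividing cells because of the VDRgem genotype stays open, and these cannot be told apart for the cell cycle genes, because VDR-null 2, at 4.37, had a lower list level than VDRgem 2, at 4.47, without carrying that genotype. The incisors' stage and how much of the apical end was dissected are not recorded.

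Whether other splits of the libraries give as many called genes was counted. For VDRgem against control 1 of the 56 splits, the real one, reached 1537 genes, and the highest other had 190. That is the smallest share these splits allow, so it argues against chance without excluding it. For VDR-null against control 1 of 100 splits drawn from 126, the real one, reached 238, and the highest other had 47. This also argues against chance without excluding it, and the splits not drawn were not counted. For VDRgem against VDR-null 1 of the 56 splits reached 3346, again the real one, which argues against chance without excluding it. The highest other, with 2606, put VDRgem 1 and 2 with VDR-null 3, so a mixed split came near the real count. Whether a structure besides genotype gave it was not tested, and the splits do not show what set the groups apart.

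By a direct test, VDRgem and VDR-null libraries differed for 3346 genes and for 13 gene lists at the preset correlation of camera (0 lists with an estimated correlation, where the smallest adjusted p was 0.52). The gene count was 434 without VDRgem 1, 13 with the keratinocyte covariate and 2221 with the GC offset, 1721 of them among the 3346. The keratinocyte covariate also takes up part of the difference between the mutants. On simulated counts with the GC trend of these libraries and 200 genes changed, 182 of 361 edgeR calls without the offset were false (50.4%). That share depends on the number of genes changed, so it does not carry over to the 3346 calls. The direct test does not tell the mutants' effects from differences between libraries in tissue or GC trend.

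Single libraries stood apart from the other 4 of their group by Dixon's gap test, with the gap given as a share of the group's range. Chance flags about 1 in 20 groups, and 18 of 258 groups tested stood out. Among controls these were mitochondrial counts in control 1 (0.848, at 0.844% against 1.04 to 1.07), the osteoclast list in control 5 (0.754), the cholesterol list in control 3 (0.843), Idi2 and Serpinb3a in control 4 (0.891 and 0.872), Postn, Col3a1 and Insig1 in control 3 (0.728, 0.823 and 0.775) and Mpc1 in control 1 (0.71). In VDR-null 2 they were the papilla list (0.84, at 3.58 against 4.38 to 4.53) and Col3a1 (0.768). In VDR-null 3 they were Myh3 (0.864) and Phospho1 (0.725), in VDR-null 4 Krt6b and Krt16 (0.881 and 0.93), and in VDR-null 1 Per1, Col5a1 and Pth1r (0.781, 0.748 and 0.747).

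The share of counts taken by the 5 most abundant genes was 20.3 ± 0.102% in VDRgem (SD, n = 3) against 17.2 ± 1.47% in control (n = 5, exact permutation p = 0.0179), and the mitochondrial share was 1.26 ± 0.123% in VDR-null (n = 5) against 1.01 ± 0.0960% in control (n = 5, exact permutation p = 0.0159). Among 44 processed copies of ribosomal protein genes the median log2 fold change was -0.53 in VDRgem (2 rose, 11 fell) and 0.10 in VDR-null (8 rose, 0 fell in edgeR), and among 83 ribosomal protein genes, not matched to these copies, it was -0.08 and -0.26.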

How the results depend on the processing

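The GC offset, the fit without VDRgem 1 and 2, the keratinocyte covariate and the region without keratin genes were added only after results were seen, the GC offset after the GC trend but before its own outcome. The cause was not tested for any of these differences.

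Counts of called genes (VDRgem against control 1537, VDR-null against control 238, VDRgem against VDR-null 3346) moved by over 1.5 times as follows. DESeq2 gave 2307 and 1657 for the comparisons with control. On counts simulated from edgeR's dispersions without a GC trend, 15.8% to 17.1% of DESeq2 calls were false against 3.26% to 5.91% for edgeR. With the GC trend of these libraries added, edgeR without the offset had 5.46% false calls in VDRgem against control. It had 22.7% in VDR-null against control and 50.4% between the mutants. For VDRgem against control limma-voom gave 981. With 1 surrogate variable the counts were 13, 2142 and 674. The stated selection, read as an unadjusted p under 0.05 with a fold floor, took 3385 and 2349. An adjusted p under 0.01 took 138, 6 and 750. In VDR-null upper-quartile scaling gave 448 and a mean of at least 1 CPM 423. Fitting only the groups compared gave 703 for VDR-null and 753 between the mutants, and the GC offset 30 and 2221. Without VDRgem 1 and 2 the counts were 5, 676 and 32, and with the keratinocyte covariate 0 (edgeR, 2507 at an unadjusted p under 0.05), 42 and 13. The covariate also takes up part of the difference between VDRgem and the other groups. Leaving out 1 library each gave 66 to 2021, 6 to 685 and 434 to 4610.

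The log2 fold change of Vdr was near 0 in VDRgem against control and changed sign with DESeq2 size factors (0.003444), without VDRgem 1 and 2 (0.11), with the covariate (0.19) and over single libraries left out (-0.20 to 0.22). In VDR-null it was 0.50 to 0.62 over single libraries left out and passed, at 0.56, without VDRgem 1 and 2. Between the mutants it was -0.75 to -0.34 over single libraries left out, -0.45 without VDRgem 1 and 2 and -0.31 with the covariate.

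For the mutants' overlap, r was 0.327 and the covariance 0.0984 without VDRgem 1 and 2, with ranges of -0.175 to 0.0815 and -0.0603 to 0.0239 over single libraries left out. Genes passing in both in the same direction numbered 162 with DESeq2, 4 with the GC offset, 1 without VDRgem 1 and 2, 0 with the covariate, 0 with controls split and 0 to 47 over single libraries. In opposite directions there were 67, 11, 4, 0, 0.55 and 3 to 55.

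Lists called by camera (20, 12 and 13) were 0, 0 and 0 with an estimated correlation, with smallest adjusted p of 0.151, 0.802 and 0.52, and 13, 1 and 5 with fry. Over single libraries left out they ranged from 13 to 21, 5 to 16 and 9 to 17. With its own score as covariate, which removes the list's signal by construction, the keratinocyte list was not called in any of the 3 comparisons. Camera adjusted p were 0.717, 0.761 and 0.725, with the direction turned. Of the 20 lists called in VDRgem 13 stayed called at the preset correlation, cell cycle, papilla, follicle and collagen among them. The others not called were immediate early (0.154), Hedgehog (0.129), osteoclast (0.698), osteoblast (0.574), muscle (0.642) and adipocyte (0.189). Between the mutants 10 of 13 stayed called, without immediate early (0.286) and osteoclast (0.445). In the same fit the log2 fold changes of Myh3 (-1.40) and Sbsn (-0.0329) changed sign in VDRgem against control. Between the mutants Fam83h (-0.18), Phospho1 (-0.0353), Nfatc1 (-0.0199), Trib3 (-0.31), Slc2a1 (-0.0161), Egln3 (-0.0637), Sbsn (-0.21) and Fabp4 (-0.11) did so.

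The odds ratio of the region around Vdr at 5 Mb, at 20 Mb and without keratin genes was 1.78, 1.33 and 1.13 for VDRgem, 1.90, 0.965 and 1.91 for VDR-null, and 1.69, 1.18 and 1.19 between the mutants. For the 206 single-gene results, 16 pairs of gene and alternative gave no value. Pseudocount and low-value filters were not applicable to the counts tested. No paired analysis was possible because the groups share no replicate pairing.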

Other observations

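Tests in this part were not planned and only describe levels. The collagen list of VDR-null 2, 3 and 5, at 11.26, 11.28 and 11.10, lay between the controls, at 10.84 to 11.06, and the VDRgem libraries, at 11.36 to 11.46. VDR-null 1, at 10.74, lay below every control, and VDR-null 4, at 10.98, lay within them. The first principal component, with 41.7% of the variance, set VDRgem 1 (112), VDRgem 2 (60.0) and VDRgem 3 (12.9) apart from each other.

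Skeletal muscle transcripts were high in VDRgem 1 and VDR-null 3, with list levels of 3.36 and 4.98, and Myh3 at 11.6 CPM in VDR-null 3. No library was grouped by these levels in any test.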
